A study of Mus musculus with 6 samples.

How the data were processed

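The series holds 6 mouse liver RNA samples of the C57BL/6 background on regular chow. Per the labels, 3 carry loxP-flanked alleles of Prkci and 3 carry the same alleles with a Cre recombinase under the albumin promoter (Alb-Cre), which acts in hepatocytes. The sample labels give an age of 30 weeks and the design text of the series gives 28 weeks. Sex, litter, cage, hour of collection and sequencing batch are not given in the sources used here. The labels number the samples 1 to 3 in each group and do not state that each came from its own animal, so p-values measure the spread between these samples. No pair of libraries held identical values.

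Per the labels' protocols, liver was frozen in liquid nitrogen, RNA was extracted with TRIzol and purified on a column, poly(A) RNA was selected, strand-preserving libraries were made with an Ultra Directional kit, and single-end reads were taken on a NextSeq instrument. Per the submitters' processing notes, the genome build was mm10 and the tools included STAR and DESeq2, whose roles and versions are not given in the sources used here. The gene annotation, the treatment of reads that match several genes and the use of strand in counting are also not given in the sources used here. Genes that share sequence or overlap are therefore named as uncertain where they appear.

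The values deposited by the authors are FPKM (fragments per kilobase of transcript, scaled to a common number of mapped fragments) for 24341 gene symbols in 6 columns, 1 per library. The unit was read from the values, since the table does not name it. FPKM divides reads by transcript length and by library total, so a gene that takes a large share of a library lowers the values of all others there. Alb, among the most abundant liver transcripts, was listed at 0 in all 6 libraries, so a value of 0 can be a failed estimate and is given only as listed at 0. In all, 7343 genes were listed at 0 in every library.

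Read totals were estimated from the steps between low FPKM values. For genes with 1 annotated transcript longer than 1500 bases and a value under 0.5 FPKM, the value times length (less 200 bases) moves in steps of 1 read. The read total behind a library came out at 14770000 to 17610000, and 56.0 to 59.3% of these low values lay within 0.05 of a whole read, where chance gives 10%. At that depth 1 read on a transcript of 2000 bases is worth 0.0316 to 0.0376 FPKM. A count test on recovered reads was not run.

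The plan was fixed before the data were examined. It put a test of counts first and, for normalized values, limma's moderated test with an intensity trend on log2(FPKM + 1). The table held FPKM, so limma was used. Genes with at least 1 FPKM in at least 3 libraries were kept, which left 10963. A log2 change is the mean of the livers labelled knockout minus the mean of the controls on this scale, which understates the change of low genes. Its standard error (SE) and its 95% interval come from limma, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. With 3 livers against 3, an exact two-sided permutation test of a single value cannot give a p under 0.1, so none is given.

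Before the data were examined, 36 gene lists were also fixed, covering pathways, clock, handling and sex-biased genes, and markers of liver cell types. Each list with at least 5 tested genes, 29 in all, was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over these lists. camera asks whether the statistics of a list's genes lie higher or lower than those of all other genes. The tests were repeated with the correlation estimated from the data, and with limma's fry, which asks whether the genes of a list move at all. The single genes of each list were also adjusted over the list alone, which does not correct for the number of lists.

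The named genes follow a rule fixed with the plan. It takes Prkci, then, per direction, the 12 genes of largest fold that pass the test, do not overlap between groups and lie in the upper part of expression in the table, split at its middle gene, (from 0.450 FPKM), without pseudogenes and unnamed loci. Where fewer pass, genes of smallest p fill each direction up to 5. It then takes, per list, up to 4 members that pass over all genes or, where none does, the 2 most abundant members. Some genes that the rule names are not reported here. Genes outside this rule were chosen after their values were seen. These are the members called over a list alone and Pnpla3, Col1a1, Saa1, Cyp4a10, Ehhadh, Sqle, Per3, Cdk9, Igfbp1, Map1lc3a and Srebf1, and the genes named only for the fit without knockout replicate 1 or for fasting. Lcn2, Mup20, Cyp4a14, Dbp, Xist and Pck1 were also chosen in this way, though the rule names them too.

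Whether the shared replicate numbers pair the samples was checked on the deviations of each library from its group mean over the tested genes. The correlations were 0.477, 0.279 and 0.283 for numbers 1, 2 and 3, and every library correlated best with the library of its own number. With 3 libraries per group only a few matchings are possible, so the numbered one can come out best by chance. The tested genes are also not independent replicates. By the rule set beforehand the numbers pair the samples, although no label says what a number stands for. A fit with the number as a block was therefore made beside the fit without it, and is given where it changes a call. Comparisons of same-numbered livers are given for some lists only and are not tests.

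The limma fit was tested on simulated data made from the 10963 genes with known changes, in 20 simulations of 3 against 3 libraries. It recovered 46.55% of genes changed 2-fold and 83.4% of those changed 4-fold, with 4.90% of calls false. In the same simulations a list of 25 genes shifted 1.5-fold was called in 20 of 20 runs, and 0 of 580 unshifted lists were called. Simulated genes varied independently, while the correlation estimated in the real lists reached 0.954 (endothelial genes). These list results therefore do not carry over to lists whose genes move together. Alternatives covered the pseudocount, the filter on low values, quantile normalization, median centring, the block, the thresholds, each library left out, both libraries of a number left out, sample quality weights, robust variance moderation and removal of short RNA features. Gene positions come from the GENCODE annotation of GRCm38, the assembly behind mm10, to which 95.7% of the symbols matched. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.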

Results

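Poly(A) RNA was profiled in 6 mouse livers. Of these, 3 were floxed controls, whose Prkci alleles carry loxP sites, and 3 were labelled as hepatocyte knockouts, in which albumin-driven Cre recombinase acts on the same alleles. Prkci encodes the atypical protein kinase C called lambda/iota, a partner of the cell polarity complex. The question, as the series title states it, concerns autophagy, oxidative phosphorylation and liver tumours when hepatocytes lack this kinase. The estimated read totals were 16540000, 15460000 and 14770000 in the control livers and 17610000, 15200000 and 16030000 in the livers labelled knockout, so depth did not separate the groups. Errors are SD over n = 3 livers unless SE is named. Where means are set against each other, the controls come first, and where single livers are listed in the order of replicates 1, 2 and 3, those labelled knockout come first unless the group is named.

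Prkci itself was at 5.57, 3.65 and 4.44 FPKM in control replicates 1, 2 and 3 and at 5.70, 5.26 and 4.42 FPKM in the corresponding livers labelled knockout. Its log2 difference was 0.15 (SE 0.17, 95% interval -0.25 to 0.55, limma with Benjamini-Hochberg adjusted p = 0.813), so a lower level was not seen, and the sign turned with sample quality weights (-0.02). Prkci lies on chromosome 3 of mm10, from 30995747 to 31052959 on the plus strand, and holds the microRNA gene Mir7008 within it. The FPKM value covers the whole gene, liver also holds cells in which albumin-Cre is not active, and the deleted part of Prkci is not given in the sources used here. This value therefore does not check the labels, and each direction given here rests on livers named by their label.

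Among 10963 tested genes, 1 was higher and 2 were lower in the livers labelled knockout (limma, Benjamini-Hochberg adjusted p under 0.05). Snora17, a small nucleolar RNA of 132 bases, was listed at 0 in the 3 controls and at 8.50, 9.85 and 9.27 FPKM in the livers labelled knockout (limma adjusted p = 3.62e-04). Mir2861, a microRNA precursor of 82 bases, stood at 56.2, 58.5 and 61.3 FPKM in the controls and was listed at 0 in all 3 others (limma adjusted p = 5.10e-06). Mup19, a major urinary protein gene, stood at 6.96, 4.76 and 5.19 FPKM in the controls against 0, 0.0977 and 0 FPKM (limma adjusted p = 0.00746).

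Snora17 lies on chromosome 2 from 26639190 to 26639321 on the minus strand and overlaps no other annotated gene. Mir2861 lies on chromosome 2 from 32712807 to 32712888, inside an exon and untranslated region of Cdk9 on the same strand, so reads from Cdk9 and Mir2861 cannot be told apart. Cdk9 was at 8.39 ± 0.496 FPKM in control livers and 9.43 ± 0.190 FPKM in those labelled knockout. Mup19, on chromosome 4 from 61778324 to 61782269, belongs to a family of near-identical copies, and its level is uncertain. With the replicate number as a block the limma adjusted p of Mup19 was 0.0551. Its call also ended without control replicate 1 (0.0510) or 3 (0.0641) and without knockout replicate 2 (0.0589) or 3 (0.0690), within a range of adjusted p from 0.000547 to 0.496 over 20 alternatives. Without both libraries numbered 3, the limma adjusted p was 0.0935 for Snora17 and 0.496 for Mup19, and without those numbered 2 it was 0.141 for Mup19. Over 20 alternatives it ranged from 2.07e-05 to 0.0935 for Snora17 and from 3.26e-07 to 0.0147 for Mir2861.

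At an unadjusted p under 0.05, limma gave 695 genes higher and 394 lower in the livers labelled knockout, 9.93% of those tested. This sum of 1089 was 1924 without knockout replicate 1, 662 without knockout replicate 2, 702 without knockout replicate 3 and 2953 with sample quality weights. The groups did not overlap for 1786 genes, or 16.3% where chance gives 10%, with 1177 of them higher and 609 lower. Over the 9 other splits of the same livers into 3 and 3 this number ran from 335 to 2532, and was at most 583 in the 3 others that part every same-numbered pair. The block raised the count at an unadjusted p under 0.05 from 1089 to 1773, with 1 gene higher and 2 lower after adjustment. Counts of called genes depended on the liver left out: 78 higher and 75 lower without knockout replicate 1, 3 higher without control replicate 2, 2 higher without control replicate 3, and 1 lower without control replicate 1, control replicate 3 or knockout replicate 2. Sample quality weights gave 311 higher and 226 lower, and a filter at 5 FPKM gave 1 lower. With short RNA features left out 0 genes were higher and 1 was lower, with 1086 at an unadjusted p under 0.05.

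Beyond these 3, the genes of smallest p that the naming rule took in each direction, with unnamed loci left out, did not pass. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was at 2.10 ± 1.49 FPKM in control livers and 20.9 ± 5.74 FPKM in those labelled knockout (log2 difference 2.89, SE 0.36). Ephx1, the microsomal epoxide hydrolase, was at 181 ± 28.3 against 435 ± 20.2 FPKM (1.27, SE 0.16). Cox6b2, an isoform of a cytochrome c oxidase subunit, was at 0.366 ± 0.132 against 2.16 ± 0.178 FPKM, and Arl4d, a small GTPase, at 12.1 ± 1.38 against 34.3 ± 7.17 FPKM. On the other side stood Cyp2c29, a cytochrome P450 of drug and fatty acid metabolism, at 868 ± 115 against 367 ± 15.5 FPKM (-1.23, SE 0.16), Sult5a1, a sulfotransferase, at 23.9 ± 3.48 against 3.14 ± 2.01 FPKM, and the antisense transcript Hnf4aos at 9.52 ± 1.49 against 2.69 ± 0.472 FPKM. For each of these 7 genes every liver labelled knockout lay beyond every control, and the limma adjusted p lay between 0.146 (Hnf4aos) and 0.176 (Sult5a1).

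Cdkn1a lies on chromosome 17 from 29090976 to 29100727, Ephx1 on chromosome 1 from 180976210 to 181020904, Cox6b2 on chromosome 7 from 4751792 to 4753094 and Arl4d on chromosome 11 from 101665541 to 101667832. Cyp2c29 lies on chromosome 19 from 39269405 to 39330713, Sult5a1 on chromosome 8 from 123140192 to 123158315 and Hnf4aos on chromosome 2 from 163493807 to 163541720. Hnf4aos runs opposite Hnf4a, and Cyp2c29 overlaps a pseudogene of its family, so their reads may be shared with these neighbours. The same holds for Ephx1, which overlaps an exon of Gm36961 on its own strand. Sult5a1 and Cdkn1a overlap Gm20388 and AC167363.2 on the other strand. Without knockout replicate 1 each of the 7 passed, with limma adjusted p from 0.0188 (Sult5a1) to 0.0457 (Arl4d).

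**Figure D1:**
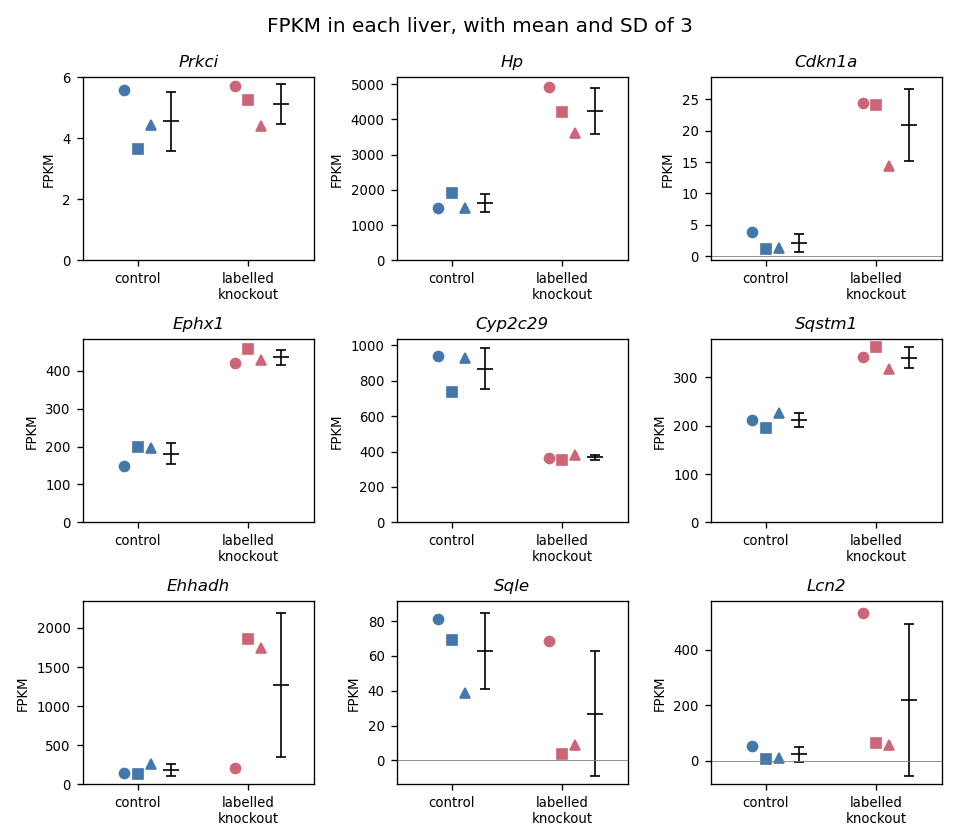
FPKM (vertical axes, linear) of 9 genes in each liver: blue marks are controls, red marks are livers labelled knockout, circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD of 3. Prkci overlaps between the groups, Cdkn1a, Ephx1, Cyp2c29, Hp and Sqstm1 do not, and knockout replicate 1 lies with the controls for Ehhadh (201 FPKM) and Sqle (68.3 FPKM) and far above the rest for Lcn2 (533 FPKM).

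Of the 29 lists tested, camera called 20, with 7 higher and 13 lower in the livers labelled knockout. Some lists share members: 7 of 26 CAR and PXR, 7 of 22 female-biased and 5 of 26 bile acid genes were also in another list. The 20 calls are therefore not independent. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.607 and 1 list had an unadjusted p under 0.05. With fry, 0 lists moved in 1 direction after Benjamini-Hochberg adjustment, 2 had an unadjusted p under 0.05 for it, and 8 changed in either direction. Among 703 different genes in the lists, limma called 0 over all genes tested, and 102 had an unadjusted p under 0.05. In the limma test adjusted over the list alone, 22 different genes passed. That adjustment does not correct for the number of lists. Over all genes tested, the limma adjusted p of these genes ran from 0.165 to 0.384, so where one is said to rise or fall it did not pass there. For immediate early, PPARA, cholesterol synthesis and female-biased genes, camera calls with the preset correlation held with any 1 liver left out.

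Autophagy genes, the first subject of the study's title, differed little in mean level. Of 44 tested genes from initiation to cargo binding, 27 were higher and 17 lower, with a mean log2 change of 0.07, and the list was not called (camera adjusted p = 0.349). The list means were 0.093, 0.059 and 0.067 in the livers labelled knockout and -0.015, 0.004 and 0.011 in the controls. The groups thus did not overlap, by a small margin. Sqstm1, which encodes the cargo receptor p62, was at 211 ± 14.8 FPKM in control livers and 341 ± 22.3 FPKM in those labelled knockout, with no overlap of the groups (log2 change 0.69, SE 0.13, limma adjusted p = 0.272). Gabarapl1, a member of the ATG8 family, was at 234 ± 51.6 against 239 ± 53.2 FPKM. Map1lc3a, of the same family, was at 30.0 ± 4.71 against 53.9 ± 15.1 FPKM (log2 difference 0.79, SE 0.24, limma adjusted p = 0.409), and passed without knockout replicate 1 (adjusted p = 0.0458). Of the list's genes 0 passed adjusted over the list alone, and 2 higher and 1 lower genes had an unadjusted p under 0.05. With fry the list had an unadjusted p of 0.0179 for 1 direction (adjusted p = 0.260) and an adjusted p of 0.0469 for either direction. Immediate early genes had a smaller unadjusted fry p for 1 direction. Of the 8 lists that fry called in either direction, autophagy and bile acid genes had the largest adjusted p. The fry adjusted p was 0.00198 for CAR and PXR targets, 0.00731 for NRF2 targets and 0.0188 for hepatocyte genes. It was 0.0262 for lysosomal genes and 0.0343 for both immediate early and male-biased genes.

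Lysosomal genes were higher by a small amount: 27 of 39 lay above the control mean, with a mean log2 change of 0.15 (camera adjusted p = 0.0193; adjusted p = 0.716 with an estimated correlation). The list means were 0.30, 0.05 and 0.10 in the livers labelled knockout and 0.04, -0.08 and 0.04 in the controls, where macrophage markers averaged 1.36, -0.30 and 0.29 and 0.72, -1.20 and 0.48. The protease gene Ctsl was at 302 ± 44.1 against 399.8 ± 73.8 FPKM, and Lamp2, a lysosomal membrane protein gene, at 356 ± 9.86 against 339 ± 16.1 FPKM. No lysosomal gene passed adjusted over the list alone, and 7 had an unadjusted p under 0.05, all higher. The camera call ended without control replicate 1 (adjusted p = 0.0578) or knockout replicate 1 (0.215). The lysosomal mean moved by over 1.5 times without knockout replicate 1 (0.08).

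Nuclear genes of the respiratory chain were marginally lower. In complex I, which oxidizes NADH, 26 of 35 genes were lower, with a mean log2 change of -0.08 (camera adjusted p = 0.0192; adjusted p = 0.716 with an estimated correlation). In complexes II to V, 24 of 40 were lower, with a mean of -0.07 (camera adjusted p = 0.0292, 0.0514 with the block; adjusted p = 0.722 with an estimated correlation). The complex I subunit gene Ndufb9 was at 376 ± 50.5 against 326 ± 36.2 FPKM and Ndufa3 at 397 ± 43.5 against 397 ± 45.2 FPKM. The ATP synthase genes Atp5b and Atp5k were at 742 ± 25.3 against 780.4 ± 58.5 FPKM and 759.6 ± 86.0 against 604 ± 44.5 FPKM. Of either list 0 genes passed adjusted over the list alone, and 0 complex I genes and 2 of complexes II to V had an unadjusted p under 0.05.

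The 2 respiratory calls ended without control replicate 2 (camera adjusted p = 0.774 for both), without knockout replicate 1 (0.820 and 0.851, where the camera direction of complexes II to V, against all other genes, turned and their mean stayed lower) and under quantile normalization (0.178 and 0.493). Mean log2 levels of complex I genes relative to the control mean were -0.14, -0.09 and 0.00 in the livers labelled knockout and -0.03, 0.15 and -0.12 in the controls, so the groups overlapped. The complex I mean moved by over 1.5 times without control replicate 2 (-0.00200), control replicate 3 (-0.14), knockout replicate 1 (-0.05) or knockout replicate 3 (-0.12). The complexes II to V mean moved by over 1.5 times without control replicate 2 (-0.00223), control replicate 3 (-0.15), knockout replicate 1 (-0.03) or knockout replicate 3 (-0.11). The 13 mitochondrially encoded subunits were not analysed here.

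Fat oxidation genes were higher and sterol synthesis genes lower, and in both lists the difference lay in knockout replicates 2 and 3. PPARA, a nuclear receptor, drives fatty acid oxidation and ketogenesis genes. Of its 40 tested targets 35 were higher, with a mean log2 change of 1.01 (camera adjusted p = 5.40e-06; adjusted p = 0.716 with an estimated correlation). The list mean relative to the controls was -0.210, 1.647 and 1.602 in the 3 livers labelled knockout. Ehhadh, a peroxisomal oxidation enzyme, was at 201, 1862 and 1739 FPKM in these livers and 178 ± 75.8 FPKM in the controls. Cyp4a14, a fatty acid hydroxylase of a multigene family, was at 82.3, 5040.0 and 3908 FPKM against 230.1 ± 174, and its relative Cyp4a10 at 94.6, 2516 and 2445 against 241 ± 199.9 FPKM. Fabp1, the liver fatty acid binding protein gene, was at 10556 ± 2264 against 10811 ± 4543 FPKM. No PPARA target passed adjusted over the list alone, and 9 had an unadjusted p under 0.05.

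All 25 tested cholesterol synthesis genes had lower means in the livers labelled knockout, with a mean log2 change of -1.24 (camera adjusted p = 1.71e-09; adjusted p = 0.716 with an estimated correlation). The list mean was 0.28, -2.27 and -1.75 in these livers, and 0.19, 0.21 and -0.40 in the controls. Sqle, which encodes squalene epoxidase, was at 68.3, 3.67 and 8.55 FPKM against 63.1 ± 21.9 FPKM in controls. Sc5d, which acts in a late step, was at 413 ± 143 against 200.3 ± 170.5 FPKM. Of its genes 0 passed adjusted over the list alone, and 2 had an unadjusted p under 0.05. Without knockout replicate 1 the mean changes were -2.01 for cholesterol synthesis and 1.62 for PPARA targets, and Sqle (0.0356), Sc5d (0.0477) and Ehhadh (0.0188) passed by limma adjusted p. Without knockout replicate 2 the mean change of cholesterol synthesis was -0.73.

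Fatty acid and triglyceride synthesis genes were lower as a list, with 18 of 27 lower and a mean log2 change of -0.56 (camera adjusted p = 0.0451; adjusted p = 0.716 with an estimated correlation). With p adjusted over the list alone, Dgat2, which makes triglycerides, fell (349 ± 38.2 against 190.5 ± 42.1 FPKM), and Pparg, a nuclear receptor of fat storage, rose (5.47 ± 1.36 against 11.7 ± 1.23 FPKM). The desaturase genes Scd1 and Fads2 were at 2226 ± 1398 against 1371 ± 1683 FPKM and 347 ± 125 against 359 ± 63.9 FPKM. The list mean was 0.38, -1.19 and -0.86 in the livers labelled knockout and 0.42, -0.38 and -0.04 in the controls, so knockout replicate 1 lay on the other side of the control mean from replicates 2 and 3, and each lay below the control of its number. Srebf1, which encodes the lipogenic factor SREBP1, was at 93.0, 5.00 and 9.42 FPKM against 93.3 ± 6.03. Pnpla3, a lipase gene, was at 47.2, 3.01 and 3.27 FPKM in controls and 11.4, 0.0739 and 0.0981 FPKM in the others, and passed only with the block (limma adjusted p = 0.0344, 0.662 without) and without both libraries numbered 1 (0.0372), within 0.0344 to 1.00 over 20 alternatives. The camera call of the list ended without control replicate 1 (0.135), control replicate 3 (0.184), knockout replicate 2 (0.0863) or knockout replicate 3 (0.0993), and with no filter (0.0542), median centring (0.0793) or quantile normalization (0.194). The fatty acid synthesis mean moved by over 1.5 times without control replicate 1 (-0.35), knockout replicate 1 (-1.03) or knockout replicate 2 (-0.24).

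Drug metabolism genes of the nuclear receptors CAR and PXR moved both ways. The list was lower, 17 of 26 genes with a mean log2 change of -0.40 (camera adjusted p = 0.00886; adjusted p = 0.716 with an estimated correlation). Among single genes adjusted over the list alone, Cyp2c29, Cyp2b10, Cyp3a44 and Sult1d1 fell and Ugt1a9, a glucuronosyltransferase gene, rose (33.7 ± 15.9 against 129 ± 18.9 FPKM). Cyp3a44 was at 251 ± 170.3 against 10.8 ± 8.17 FPKM, Cyp2b10 at 10.6 ± 3.83 against 2.36 ± 2.36 FPKM and Sult1d1 at 103 ± 9.32 against 53.1 ± 13.7 FPKM. Cyp3a11, the most abundant member over all 6 livers, spread widely in controls (49.5, 1349 and 316 FPKM) and was at 1698, 1433 and 1211 FPKM in the livers labelled knockout. Several of these belong to multigene families whose reads may be shared. The camera call ended without control replicate 2 (0.0800), control replicate 3 (0.0755) or knockout replicate 1 (0.187) and under quantile normalization (0.0578). The CAR and PXR target mean moved by over 1.5 times without control replicate 1 (-0.61).

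NRF2 targets, genes of antioxidant defence, were higher: 22 of 31, with a mean log2 change of 0.24 (camera adjusted p = 0.0262; adjusted p = 0.716 with an estimated correlation). In the limma test adjusted over the list alone, Ephx1 and Srxn1 rose, the latter, sulfiredoxin, with 17.6 ± 5.59 against 52.0 ± 16.8 FPKM. The ferritin genes Ftl1 and Fth1 were at 1920.2 ± 91.0 against 2877 ± 257 FPKM and 1544 ± 82.4 against 1787 ± 127 FPKM. The list mean was 0.90, -0.12 and -0.06 in the 3 livers labelled knockout and 0.17, -0.19 and 0.02 in the controls. Knockout replicate 3 thus lay below the control of its number. The camera call ended without knockout replicate 1 (adjusted p = 0.970) or control replicate 2 (0.0920). The NRF2 target mean moved by over 1.5 times without control replicate 2 (0.15), knockout replicate 1 (-0.09), knockout replicate 2 (0.42) or knockout replicate 3 (0.39).

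Bile acid genes were lower as a list, 15 of 26, with a mean log2 change of -0.10 (camera adjusted p = 0.0385, 0.0591 with the block; adjusted p = 0.716 with an estimated correlation). With p adjusted over the list alone, the phospholipid exporter gene Abcb4 rose (78.3 ± 13.6 against 211 ± 73.8 FPKM) and the sterol exporter gene Abcg8 fell (56.6 ± 2.25 against 36.6 ± 2.85 FPKM). Cyp2c70, which makes muricholic acids, was at 597, 44.4 and 54.7 FPKM against 1176, 432 and 529 FPKM in controls, and Slc27a5, a bile acid ligase gene, at 525 ± 90.2 against 422 ± 78.2 FPKM. The camera call ended without control replicate 2 (0.218), control replicate 3 (0.192) or knockout replicate 1 (0.726), and with median centring (0.105) or quantile normalization (0.191). The bile acid mean moved by over 1.5 times without control replicate 1 (-0.19), control replicate 2 (-0.05) or control replicate 3 (-0.06).

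Glucose metabolism genes were higher, 21 of 29, with a mean log2 change of 0.23 (camera adjusted p = 0.0474; adjusted p = 0.716 with an estimated correlation). Pck1, the gluconeogenic carboxykinase gene, was at 898, 2764 and 2064 FPKM against 760.4 ± 274. No member passed adjusted over the list alone, and 8 higher and 1 lower had an unadjusted p under 0.05. The camera call ended without control replicate 2 (0.281), knockout replicate 1 (0.117) or knockout replicate 3 (0.0779), and with no filter (0.0508). The glucose metabolism mean moved by over 1.5 times without control replicate 2 (0.11).

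In the unfolded protein response list the chaperone genes Calr and Hsp90b1 were at 460.4 ± 55.4 against 358 ± 71.6 FPKM and 445 ± 34.8 against 341 ± 41.2 FPKM. The list was lower, 17 of 24 genes, with a mean log2 change of -0.09 (camera adjusted p = 0.0419; adjusted p = 0.716 with an estimated correlation). No member passed adjusted over the list alone, and 3 higher and 1 lower had an unadjusted p under 0.05. This call ended without control replicate 2 (camera adjusted p = 0.408), knockout replicate 1 (0.0639) or knockout replicate 3 (0.586), and with median centring (0.0652) or quantile normalization (0.194). The unfolded protein response mean moved by over 1.5 times without control replicate 2 (-0.01), control replicate 3 (-0.15), knockout replicate 1 (-0.21) or knockout replicate 3 (0.08).

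Inflammation and matrix genes were higher, most of all in knockout replicate 1. Of 27 acute phase and inflammation genes 20 were higher, with a mean log2 change of 0.56 (camera adjusted p = 0.0170; adjusted p = 0.716 with an estimated correlation). Among single genes adjusted over the list alone, Hp, which encodes haptoglobin, rose (1634 ± 252 against 4248 ± 650.3 FPKM). Hpx, hemopexin, was at 2642 ± 534 against 4539 ± 1774 FPKM, and Fgb, a fibrinogen chain gene, at 3634 ± 668 against 2475 ± 284 FPKM. Of 19 extracellular matrix genes 18 were higher, with a mean of 0.58 (camera adjusted p = 0.00458; adjusted p = 0.716 with an estimated correlation). The collagenase activator gene Mmp14 was at 20.5 ± 5.88 against 32.6 ± 3.54 FPKM, and Fn1, fibronectin, at 354 ± 87.6 against 317 ± 16.6 FPKM. No matrix gene passed adjusted over the list alone, and 3 had an unadjusted p under 0.05.

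The means of these lists were 1.35, 0.03 and 0.31 for inflammation and 1.41, 0.19 and 0.15 for matrix in the 3 livers labelled knockout, and 0.44, -0.34 and -0.10 and 0.46, -0.37 and -0.09 in the controls. In both lists each liver labelled knockout lay above the control of its number. Macrophage markers averaged 1.36, -0.30 and 0.29 in the livers labelled knockout and 0.72, -1.20 and 0.48 in the controls. For these markers knockout replicate 3 lay below the control of its number. Both camera calls ended without knockout replicate 1 (0.398 and 0.215) or control replicate 2 (0.0587 and 0.0862). The inflammation mean moved by over 1.5 times without knockout replicate 1 (0.17). The matrix mean moved by over 1.5 times without knockout replicate 1 (0.17).

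Interferon-induced genes were lower, 26 of 36, with a mean log2 change of -0.21 (camera adjusted p = 0.0110; adjusted p = 0.722 with an estimated correlation). Bst2, which tethers virus particles, was at 216 ± 17.6 against 205 ± 122 FPKM, and Iigp1, an interferon-induced GTPase gene, at 141 ± 12.6 against 101 ± 28.2 FPKM. Of these genes 0 passed adjusted over the list alone and 0 had an unadjusted p under 0.05. The list mean was 0.44, -0.98 and -0.09 in the livers labelled knockout. The camera call ended without control replicate 1 (0.173) and ended with the camera direction turned without knockout replicate 2 (0.601). The interferon response mean moved by over 1.5 times without control replicate 1 (-0.01), control replicate 2 (-0.41), knockout replicate 1 (-0.53) or knockout replicate 2 (0.18).

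Genes of liver tumours and fetal liver were not called, with 10 of 16 higher and a mean log2 change of 0.68 (camera adjusted p = 0.180). Only 16 of the 30 members passed the filter on low values, so the result does not cover the members below it. The list means were 1.75, 0.08 and 0.23 in the livers labelled knockout and 0.65, -0.45 and -0.20 in the controls. The groups overlapped, while each liver labelled knockout lay above the control of its number. Ly6d was at 608, 69.0 and 102 FPKM against 65.9, 1.45 and 1.66 in controls, and Lcn2, lipocalin 2, at 533, 62.1 and 57.6 against 53.9, 5.26 and 10.2 FPKM. The list was called higher without control replicate 1 (0.0234; adjusted p = 0.732 with an estimated correlation and all 6 livers), knockout replicate 2 (0.0185) or knockout replicate 3 (0.0472), and its camera direction, against all other genes, turned without knockout replicate 1 (0.820) and with no filter (0.869), while its mean change stayed above 0 (0.15 and 0.36). Of its genes 0 passed adjusted over the list alone, and 4 had an unadjusted p under 0.05.

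Cell cycle genes were not called (camera adjusted p = 0.473, 10 of 15 higher, mean 0.19). Only 15 of the 33 members passed the filter on low values, so this result does not cover the members below it. In the limma test adjusted over the list alone, the inhibitor gene Cdkn1a rose and Tk1, thymidine kinase, fell (21.9 ± 6.23 against 5.98 ± 3.81 FPKM). Ccnd1, cyclin D1, was at 45.8 ± 8.01 against 69.1 ± 19.7 FPKM, and Pcna, a replication clamp gene, at 16.1 ± 0.850 against 15.1 ± 2.70 FPKM. The list was called higher without knockout replicate 2 (0.0364; adjusted p = 0.850 with an estimated correlation and all 6 livers) and with no filter (0.0235), and the camera direction turned without knockout replicate 1 (0.436), as did the mean (-0.07).

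Protein kinase C and polarity genes, the family of Prkci, were not called (camera adjusted p = 0.653, 14 of 22 higher, mean 0.07), with 0 genes passing adjusted over the list alone and 1 at an unadjusted p under 0.05. Cdc42 was at 86.75 ± 12.99 against 89.10 ± 26.12 FPKM, and Cldn1, a tight junction gene, at 21.9 ± 7.35 against 23.8 ± 8.72 FPKM. The camera direction turned without knockout replicate 1 (0.820), as did the mean (-0.07).

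Immediate early and heat shock genes, which respond within minutes to handling, were higher in all 3 livers labelled knockout. All 20 tested genes had higher means, by 0.87 on the log2 scale on average (camera adjusted p = 2.62e-06; adjusted p = 0.607 with an estimated correlation). The list means were 0.85, 1.18 and 0.57 in these livers and 0.27, -0.15 and -0.12 in the controls. With p adjusted over the list alone, the transcription factor genes Nr4a1, Jun and Jund and the co-chaperone gene Dnajb1 rose. Nr4a1 was at 5.11, 51.8 and 11.4 FPKM against 1.94, 0.739 and 0.684, Jun at 17.0, 43.6 and 9.38 against 6.82, 3.27 and 3.31, and Jund at 20.7 ± 2.90 against 38.1 ± 7.51 FPKM. Hspa8, a heat shock protein gene, was at 264 ± 30.5 against 444 ± 114 FPKM, and Zfp36 at 43.60 ± 13.05 against 59.93 ± 16.73 FPKM.

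Clock genes, which follow the hour of collection, were lower as a list, 14 of 18, with a mean log2 change of -0.32 (camera adjusted p = 0.00886; adjusted p = 0.716 with an estimated correlation). Dbp, a clock output gene, was at 37.5, 7.62 and 49.2 FPKM against 34.3, 84.8 and 88.1, Per3 at 4.86, 1.15 and 4.90 against 5.55, 10.2 and 11.5, and Bhlhe40 at 73.5 ± 37.0 against 50.8 ± 42.3 FPKM. Of these genes 0 passed adjusted over the list alone, and 2 had an unadjusted p under 0.05. The camera call ended without control replicate 2 (0.0800), control replicate 3 (0.0864) or knockout replicate 1 (0.205). The clock gene mean moved by over 1.5 times without control replicate 1 (-0.51) or knockout replicate 2 (-0.19).

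Genes that differ between the sexes in mouse liver were lower in both lists. Female-biased genes averaged -1.10, with 20 of 22 lower (camera adjusted p = 3.75e-05; adjusted p = 0.716 with an estimated correlation), and Cyp3a44 fell adjusted over the list alone, while Cyp2a4 was at 1011 ± 701 against 561 ± 364 FPKM. The female-biased list means were -2.12, -0.92 and -0.26 in the livers labelled knockout and 0.08, -0.74 and 0.66 in the controls, so the groups overlapped while each liver labelled knockout lay below the control of its number, and the mean change was -0.59 without knockout replicate 1. Male-biased genes averaged -0.36, with 8 of 12 lower (camera adjusted p = 0.0167, 0.0518 with the block; adjusted p = 0.716 with an estimated correlation). Mup3, a urinary protein gene, and Ugt2b1 fell adjusted over the list alone (2049 ± 783 against 613 ± 281 FPKM and 112 ± 27.2 against 49.9 ± 7.67 FPKM), while Mup20 was at 1676, 135 and 96.0 FPKM against 35.0, 103 and 24.4 in controls. The male-biased call ended without control replicate 2 (0.184), with median centring (0.0672) and with quantile normalization (0.0564). The male-biased mean moved by over 1.5 times without control replicate 1 (-0.59), control replicate 2 (0.03), knockout replicate 1 (-0.63) or knockout replicate 3 (-0.19). Xist was at 52.9, 56.3 and 36.1 FPKM in controls and 47.9, 34.6 and 39.1 FPKM in the others. The Y-linked genes Ddx3y, Kdm5d and Uty were listed at 0 in all 6 livers, and Eif2s3y reached at most 0.0795 FPKM. Xist was thus present and these Y-linked genes were at or near 0 in every liver, which gives no sign of a sex difference between the groups.

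Hepatocyte genes were lower as a list, 12 of 19, with a mean log2 change of -0.24 (camera adjusted p = 0.00191; adjusted p = 0.716 with an estimated correlation). Among single genes adjusted over the list alone, Serpina1c, an antitrypsin gene of a multigene family, fell (1169 ± 62.0 against 633 ± 56.3 FPKM). Trf, transferrin, was at 8372 ± 474 against 10731 ± 4261 FPKM, and Apoa1 at 8253 ± 4069.7 against 8962 ± 4329 FPKM. Pericentral genes were lower, 16 of 20, with a mean of -0.34 (camera adjusted p = 0.00886; adjusted p = 0.716 with an estimated correlation), with Rgn at 1353 ± 411 against 497 ± 239 FPKM and Cyp2e1 at 4084 ± 1529 against 3582 ± 2064 FPKM. No pericentral gene passed adjusted over the list alone, and 2 had an unadjusted p under 0.05. The hepatocyte call ended without knockout replicate 1 (0.440), and the pericentral call without knockout replicate 1 (0.820), control replicate 2 (0.0645) or control replicate 3 (0.0755) and under quantile normalization (0.0567). The hepatocyte mean moved by over 1.5 times without control replicate 2 (-0.14), knockout replicate 1 (-0.08) or knockout replicate 2 (-0.37). The pericentral mean moved by over 1.5 times without control replicate 1 (-0.52), knockout replicate 1 (-0.11) or knockout replicate 3 (-0.56).

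Periportal genes were not called (camera adjusted p = 0.310), and their measures differed in sign: the mean log2 change was 0.15, the median -0.14 and the camera direction lower, which turned under quantile normalization (0.795) and without knockout replicate 1 (0.851). The list was called without control replicate 1 (0.0260; adjusted p = 0.716 with an estimated correlation and all 6 livers). In the limma test adjusted over the list alone, Hsd17b13, a lipid droplet protein gene, rose (259 ± 25.6 against 584 ± 158 FPKM), and 3 higher and 2 lower members had an unadjusted p under 0.05.

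Markers of other liver cells were not called. Of the 20 T and NK cell members, 6 were tested. Kupffer cell and macrophage genes averaged 0.45 over 19 genes (camera adjusted p = 0.180, 0.0283 with the block), with Lyz2 at 249, 66.4 and 82.9 FPKM against 98.7, 25.5 and 111, and Cd5l at 81.6 ± 52.2 against 98.7 ± 62.5 FPKM. T and NK cell genes averaged 0.42 over 6 (0.18 without control replicate 2, 0.20 without knockout replicate 1 and 0.72 without knockout replicate 2; camera adjusted p = 0.180, 0.0277 with the block), with the chemokine gene Ccl5 at 3.35 ± 1.41 against 10.1 ± 5.31 FPKM and Nkg7 at 1.04 ± 0.814 against 2.28 ± 1.93 FPKM. With the block both lists were called higher, with adjusted p above 0.05 for every list with an estimated correlation. Endothelial genes averaged -0.05 over 20 (camera adjusted p = 0.446), with Clec4g at 71.8 ± 36.2 against 61.8 ± 25.9 FPKM and Fcgr2b at 53.2 ± 28.6 against 41.4 ± 15.1 FPKM. Stellate cell genes averaged -0.06 over 17 (camera adjusted p = 0.192), with Dcn at 92.53 ± 13.02 against 95.48 ± 27.00 FPKM and Ecm1 at 67.0 ± 10.8 against 49.1 ± 11.7 FPKM. In these 4 lists 0 genes passed adjusted over the list alone, and 1, Ccl5, had an unadjusted p under 0.05.

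Single livers changed these marker calls. Macrophage genes were called higher without control replicate 1 (camera adjusted p = 0.0173), control replicate 3 (0.0339) or knockout replicate 2 (0.00625), also with median centring (0.0394), and the camera direction turned without control replicate 2 (0.218). T and NK cell genes were called higher without knockout replicate 2 (0.00273). Endothelial and stellate genes were called lower without control replicate 2 (4.56e-08 and 0.00456), and the endothelial camera direction turned without control replicate 1 (0.471) or 3 (0.449). The mean change took the other sign without control replicate 2 (-0.15) or knockout replicate 1 (-0.00826) for macrophage genes, without control replicate 1 (0.22), control replicate 3 (0.16), knockout replicate 2 (0.07) or knockout replicate 3 (0.08) for endothelial genes and without control replicate 1 (0.10) or knockout replicate 3 (0.05) for stellate genes. With all 6 livers the adjusted p with an estimated correlation was 0.794 for macrophage, 0.722 for T and NK cell, 0.850 for endothelial and 0.732 for stellate genes. In control replicate 2 endothelial markers averaged -0.96 and macrophage markers -1.20 relative to the control mean.

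The other marker lists had under 5 tested genes and were not tested as lists. The neutrophil genes S100a8 and S100a9 were at 139, 5.54 and 4.27 and 117, 2.27 and 7.04 FPKM in the livers labelled knockout, against 13.1, 4.09 and 5.34 and 11.2, 1.01 and 3.61 FPKM in controls. The bile duct gene Spp1 was at 42.0 ± 14.3 against 57.0 ± 74.9 FPKM. The plasma and B cell genes Jchain and Cd79b were at 6.25 ± 1.68 against 8.98 ± 0.539 FPKM and 1.06 ± 0.433 against 1.63 ± 0.327 FPKM. The globin genes Hba-a1 and Hbb-bt, of near-identical families, were at 49.1 ± 30.6 against 102 ± 27.3 FPKM and 14.6 ± 9.72 against 28.0 ± 14.5 FPKM. Of genes typical of other tissues, Fabp4 of fat was at 12.8 ± 1.57 against 16.0 ± 5.51 FPKM and Cela1 of pancreas at 11.01 ± 1.281 against 6.254 ± 2.220 FPKM. In these lists 0 genes passed adjusted over the list alone, and Jchain, Hba-a1 and Cela1 had an unadjusted p under 0.05.

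**Figure D2:**
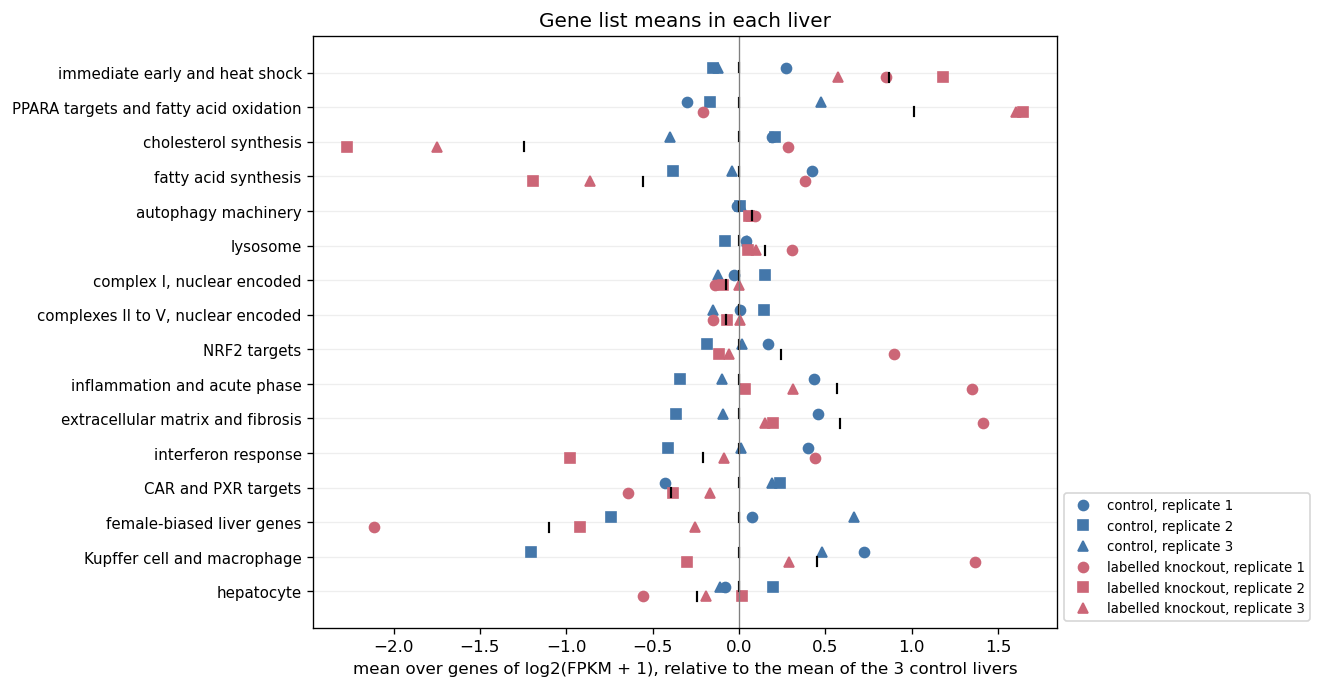
Mean over the tested genes of 16 lists of log2(FPKM + 1) relative to the mean of the 3 control livers (horizontal axis, log2), with 1 mark per liver: blue marks are controls, red marks are livers labelled knockout, shapes are replicates, and black ticks are group means. Immediate early genes lie above all controls in each liver labelled knockout (0.85, 1.18 and 0.57), while cholesterol synthesis (0.28, -2.27 and -1.75) and PPARA targets (-0.210, 1.647 and 1.602) lie far from the controls in replicates 2 and 3 and near them in replicate 1.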

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

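The tests with sample quality weights, robust moderation, removal of short RNA features, the filter at 5 FPKM, the settings without both libraries of a number, and the scalings of the lists were chosen only after the data were seen. Count-based alternatives (other size factors, count filters, count models, voom and its weights, a test of recovered reads) were not run, because the table holds FPKM. Mir2861, Mup19 and Snora17 remained called with pseudocounts of 0.1 and 5, no filter, quantile normalization, median centring, a threshold of 0.1 and a fold above 1.5. Scaling moved the median change of all genes by less than 0.1 on the log2 scale. Depth sets a step of 0.0316 to 0.0376 FPKM per read on 2000 bases, and whether it limits calls was not tested.

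Called genes numbered 1 to 78 higher and 1 to 75 lower over single livers and numbers left out, the highest without knockout replicate 1. Sample quality weights gave 311 higher and 226 lower with a weight of 8.30 on knockout replicate 3. With short features left out 0 were higher and 1 lower, by construction, and at 5 FPKM 1 was lower. Called lists numbered 7 to 22 with libraries left out, 12 under quantile normalization, 0 with an estimated correlation, 0 with fry in 1 direction and 8 in either. The block gave 19 lists and 1 higher and 2 lower genes. It ended the calls of Mup19, complexes II to V, bile acid and male-biased genes, added Pnpla3 (-1.94), macrophage and T and NK cell genes, and changed no other call.

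Prkci ranged from 0.01 to 0.28 with libraries left out and was -0.0222 with quality weights. Directions of genes with no call also turned with quality weights (Cdc42 -0.21, Cldn1 -0.31, Cyp2e1 0.38, Dcn -0.36, Fabp1 0.40, Fabp4 -0.0152, Ndufa3 0.14, S100a8 -0.41), median centring (Cdc42 -0.0456, Dcn -0.0420, Gabarapl1 -0.0271) and quantile normalization (Ndufa3 0.0184). The camera direction, against all other genes, turned for periportal genes under quantile normalization (mean 0.18) and the liver cancer list with no filter (mean 0.36), where the means kept their sign. With libraries left out 18 genes turned: Apoa1 -0.27 to 0.51, Bst2 -0.70 to 0.18, Cd5l -0.37 to 0.86, Cdc42 -0.22 to 0.14, Cldn1 -0.19 to 0.43, Clec4g -0.63 to 0.20, Cyp2e1 -0.74 to 0.28, Dcn -0.18 to 0.23, Fabp1 -0.30 to 0.37, Fads2 -0.23 to 0.33, Fcgr2b -0.78 to 0.15, Fn1 -0.35 to 0.00225, Gabarapl1 -0.14 to 0.23, Ndufa3 -0.10 to 0.10, Pcna -0.23 to 0.0243, S100a8 -0.39 to 1.98, Spp1 -1.48 to 0.23, Trf -0.0504 to 0.52. The camera direction turned for 8 lists, with means of the following ranges: complexes II to V -0.19 to -0.00223, liver cancer and fetal liver 0.15 to 1.01, cell cycle -0.0730 to 0.38, interferon response -0.53 to 0.18, atypical PKC and cell polarity -0.0698 to 0.16, periportal hepatocyte 0.0798 to 0.22, liver endothelial cell -0.53 to 0.29, Kupffer cell and macrophage -0.15 to 0.83. Of these, complexes II to V, liver cancer and periportal means kept their sign. The means, not the camera direction, of NRF2 targets (-0.09 without knockout replicate 1), unfolded protein response (0.08 without knockout replicate 3), male-biased (0.03 without control replicate 2), stellate genes (0.10 without control replicate 1, 0.05 without knockout replicate 3) and complex I (0.00604 without both libraries numbered 2) also turned. The cause was not tested.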

Other observations

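Here the tests of fasting genes and of lists over splits were chosen before their results were seen, and all other tests only after.

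Knockout replicates 2 and 3 were the most alike of the 15 pairs of livers (Spearman 0.976 across 10963 genes, which are not independent replicates), while knockout replicate 1 was closest to control replicate 1 (0.958, against 0.924 and 0.943 to the other livers labelled knockout). Without knockout replicate 1, limma called 78 genes higher and 75 lower. The lower genes held 14 of 25 tested cholesterol synthesis genes, where 0.171 would fall in that list by chance, among them Mvk, Idi1, Fdft1, Sqle, Lss, Cyp51 and Dhcr7. The higher genes held 10 of 40 PPARA targets against 0.285 by chance, among them Hadha, Hadhb, Ehhadh, Acot2, Fgf21 and Cidec. These chance counts take genes as independent, while the estimated correlation between genes was 0.848 and 0.762 in these lists, with which their camera adjusted p over all 6 livers was 0.716. In that fit knockout replicate 1 lay apart from replicates 2 and 3 in both lists. No estimated correlation was computed without that liver, so how far it would weaken these counts was not tested.

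Knockout replicate 1 held the highest levels of the 6 livers for Saa1, Col1a1 and Spp1, singled out after their values were seen, but not for Fn1 (337 FPKM, against 411 in control replicate 1) or Fgb (2403 FPKM, against 2909.5 or more in controls). Saa1, an acute phase gene, was at 615 FPKM there against 75.05 and 206 in the other livers labelled knockout and 57.3 ± 24.9 in controls. Col1a1, a collagen gene, was at 13.3 FPKM against 1.07 and 3.18, and 0.873 ± 0.582 in controls. Spp1, osteopontin, was at 144 FPKM against 13.5 and 14.03. Female-biased genes averaged -2.12 in this liver relative to the controls, while Mup20 reached 1676 FPKM.

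Of the 3 called genes, Snora17 and Mir2861 are short features. Their nonzero values multiplied by the read total of each library agreed within 0.521% for Snora17 and 1.76% for Mir2861, as equal numbers of whole reads would give. At full feature length they would stand for 19.6 to 19.8 and 74.2 to 76.2 reads. Both features, of 132 and 82 bases, are shorter than the 200 bases taken off transcripts in estimating read totals, so these read numbers are not firm. Whether a few reads on a very short feature account for both calls stays open without the effective lengths. Values even within 5% were found in 4.68% of genes in controls and 5.15% in the livers labelled knockout. What remains open is why the groups differ in which livers carry them. Mup19 is not of this kind, but its reads may belong to other Mup genes, which was not tested.

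Knockout replicate 1 stands apart from replicates 2 and 3. A lower share of hepatocytes there would raise markers of all other cells alike. Macrophage markers stood above the control mean by 1.36 (SE over genes 0.18), endothelial by 0.45 (0.05) and stellate by 0.24 (0.13). Hepatocyte markers stood at -0.56 (0.17), and 19, 20, 17 and 19 genes entered. The gap between macrophage and endothelial markers was 0.91. These SE are over genes of a single liver and do not measure the spread between livers. Genes of these lists also moved together (estimated correlation 0.842 for macrophage and 0.954 for endothelial genes). In knockout replicate 3 macrophage and endothelial markers lay apart too, at 0.29 and -0.30. The gap therefore does not decide whether a lower hepatocyte share was the whole cause. A control liver under a knockout label could not be told apart: among genes where replicates 2 and 3 lay lower than 3 of the other 4 livers, knockout replicate 1 shared their side less often than control replicate 2 (27.7 against 57.8%, or -30.2 points), while among higher genes it did so more often than any control, by 18.2 points. Against control replicate 1, of its own number, it shared that side more often in both directions (58.6 against 16.5% higher, 27.7 against 16.6% lower), and among genes called without it, it lay on that side of the control mean for 55 of 78 higher and 51 of 75 lower genes, but a median of 0.20 and 0.14 of the way, where control replicate 2, held out likewise, lay 0.09 and 0.17 of the way and control replicate 3 lay 0.31 and 0.32, with 0 genes called and so no position for control replicate 1. A condition shared by the livers numbered 1 also stays open. Their deviations correlated (0.477), the block raised the genes at an unadjusted p under 0.05 from 1089 to 1773, and 32 genes were called without both. The block left 3 called genes. It fits all numbers and leaves less data to estimate the spread from, so this count does not decide the question. A response of this animal was not tested.

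Lower cholesterol synthesis and higher PPARA target levels in knockout replicates 2 and 3 could reflect food intake before collection. The mean of 12 fasting-induced genes outside the PPARA list, among them Pck1, Igfbp1 and Tat, exceeded the highest control by at least 0.39 (log2) in these livers, at 0.93 and 0.54 against 0.16. It was also above the controls in knockout replicate 1, at 0.34, so the test does not settle it. The members did not move as 1, since Igfbp1 was at 532 and 90.6 FPKM against 31.3 or less in controls, while Gls2 (118 and 157 FPKM against 201 or more) and Hal (168 and 157 against 194 or more) lay below every control in replicates 2 and 3. Loss of Prkci stays open and untested. Over 18 clock genes knockout replicate 3 lay 1.05 (root mean square log2 difference) from knockout replicate 2. From control replicates 1, 2 and 3 it lay 0.89, 0.53 and 0.67, so its nearest control was closer by 0.52. These distances go against 1 hour shared by knockout replicates 2 and 3 and unlike that of all controls. Hours that differed between these livers stay open, so the hour of collection is not excluded.

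The 6 livers can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split called 3 genes, reached by 1 of the 10 splits, itself, and the highest other split called 2. It called 20 lists, a number reached by 3 of the 10, with 21 in the highest other split. Among the 4 splits that part all numbered pairs, the highest others called 2 genes and 13 lists. The other splits keep 2 same-numbered pairs together. The split of control replicates 1 and 3 with knockout replicate 1 against the rest gave 1817 genes at an unadjusted p under 0.05 against 1089 for the split by label, and 2532 genes apart against 1786, which points to a structure of the samples beside the labels. It keeps 2 numbered pairs together, and the splits that part all pairs gave at most 245 and 583 beside the split by label.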
